A study of Arabidopsis thaliana with 12 samples.

How the data were processed

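Messenger RNA abundance was measured by sequencing in 12 rosette samples of Arabidopsis thaliana of the Ws-0 accession, 3 biological replicates in each of 4 groups. The groups were wild type, the lsd1-1 mutant, a line that expresses LSD1 fused to green fluorescent protein from the 35S promoter (LSD1-GFP), and a line that expresses LSD1 fused to the glucocorticoid receptor domain from the same promoter and was treated with dexamethasone (LSD1-GR+DEX). Plants were 2 weeks old and grew with 16 h of light per day. Only the LSD1-GR seedlings grew on nylon mesh, as the treatment was described, and were moved to medium with 30 µM dexamethasone before RNA was isolated. The series holds no untreated LSD1-GR sample and no wild-type sample moved to dexamethasone, so the transgene, the hormone analog and the transfer change together in this group. The hour of harvest and the time spent on dexamethasone are not given in the sources used here.

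Libraries were made with a stranded messenger RNA kit. Per the labels, the authors used Trimmomatic 0.30, GSNAP, HTSeq 0.6.1 and the TAIR10 genome. The settings of trimming, alignment and counting, the strand setting among them, and the treatment of reads that match several genes are not given in the sources used here. The deposited table holds raw counts for 27416 gene models, each named by a transcript identifier, with no normalization. All values were whole numbers, and each library had its own total. Total counts ran from 9781360 to 11503432 per library, and 21916 to 22284 genes had at least 1 count. Of the loci in the table, 26719 were found in the reference annotation of the TAIR10.1 assembly, which supplied symbols and positions.

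Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr, which left 19487 genes, and library sizes were scaled by TMM factors. All 12 libraries entered 1 model with a mean for each group (robust quasi-likelihood fit, biological coefficient of variation 11.2%). Each contrast was tested two-sided with edgeR's quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p below 0.05. The standard error (SE) of a log2 difference was its size divided by the square root of F. Levels are TMM-scaled CPM, counts over the scaled library size as edgeR's cpm function gives them, printed as mean ± SD over the 3 libraries of a group. Where a group had 1 to 3 counts in all, the ratio of summed counts is given with a 95% exact binomial counting interval, and where it had 0, the fold is a lower bound against a floor of 3 counts over the group. Intervals and floors cover counting error only.

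The 23 gene lists, the 4 comparisons, their tests, the rule for named genes and all alternatives but 1 were chosen before the data were examined. Tests of explanations for single patterns, and 2 further lists prompted by single genes, came later. The 23 lists hold 363 loci and were written from textbook knowledge. They cover salicylic acid immunity, cell death regulators, antioxidant enzymes, oxidative stress markers, nuclear photosynthesis genes, auxin response, the MYC2 branch of jasmonate response, ethylene and jasmonate defence, abscisic acid with cold and drought, heat shock and protein folding, glucosinolate and camalexin synthesis, anthocyanin and flavonoid synthesis, cell cycle, cell wall and touch response, circadian clock, iron deficiency, phosphate starvation, senescence and starvation, floral transition, and markers of root, guard cell, vascular and epidermal or cuticle tissue. Of 365 list entries, 1 (GRXC9) was left out because its locus and symbol did not match in the reference, and 7 loci had no symbol there. A list was called moved when limma 3.58.1's camera test with a preset correlation of 0.01 gave an adjusted p below 0.05, adjusted over 92 tests (23 lists in 4 comparisons). Beside it stand camera with a correlation estimated for each list and the number of members called, over all genes and adjusted over the list alone. Genes were named by this rule: LSD1, the 6 largest rises and 6 largest falls among called genes with at least 5 CPM in the higher group and no overlap between replicates, up to 4 members with the lowest adjusted p of each list with a called member, and PR1, PDF1.2, CSD1, CSD2, RBCS1A and CAT2. Not every gene that the rule takes is named in the text.

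Relations between contrasts are correlations across genes, which are not independent replicates, and overlaps of called genes. They were set beside 30 simulations of unchanged groups tested against the same wild-type libraries. Alternatives were edgeR's RLE size factors in place of TMM, the DESeq2 1.42.0 Wald test, limma voom and no low-count filter. Others were a filter of at least 5 CPM in 3 libraries, a fit of the 2 compared groups alone and replicate number as a block. A test against a 1.5-fold change (glmTreat), each library left out in turn, and fry for the lists were also used. The relation between contrasts that share no library was added after the data were seen. Whether replicate numbers pair the libraries was read from the correlation of same-numbered libraries in their deviations from the group means, since the labels give only the numbers. It was 0.168 to 0.388 for lsd1-1 with wild type and 0.208 to 0.469 for LSD1-GFP with wild type, where every pair was above 0.1. On simulated data with 100 genes changed 2-fold and 100 changed 4-fold, the test recovered 76% to 84% of the former and 96% to 97% of the latter, and called 7 to 19 unchanged genes per comparison. Differences between chloroplast or mitochondrial transcripts were not analysed here, since messenger RNA libraries hold few of them.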

Results

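Rosette transcripts of wild-type Arabidopsis, the lsd1-1 mutant and 2 lines that overexpress LSD1 fusions were counted in 3 libraries per group. Each of the 12 libraries held between 9781360 and 11503432 counts. In the order of replicates 1 to 3 these were 9790305, 10735542 and 10489337 in wild type and 9781360, 10634636 and 10934277 in lsd1-1. They were 10579567, 11503432 and 10753620 in LSD1-GFP and 10860683, 10580521 and 10299746 in LSD1-GR+DEX.

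LSD1, a zinc finger protein known as a brake on spreading cell death, differed between the groups as the line names state. In wild type its transcript stood at 23.57 ± 1.88 CPM (mean ± SD, n = 3). In lsd1-1 it stood at 0.094 ± 0.093 CPM, with 3 counts in all against 756 in wild type, which is 0.394% of the wild-type level (95% counting interval 0.0811% to 1.16%). In LSD1-GFP it rose 99.7-fold to 2351 ± 305 CPM (log2 difference 6.64, SE 0.18, adjusted p = 5.55e-11). In LSD1-GR+DEX it rose 7.55-fold to 178 ± 36.8 CPM (2.92, SE 0.16, adjusted p = 7.96e-08). LSD1 (AT4G20380) lies on chromosome 4 at 11004503 to 11006968 of TAIR10.1, on the plus strand, and the counts do not separate transgene from resident transcript.

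**Figure D1:**
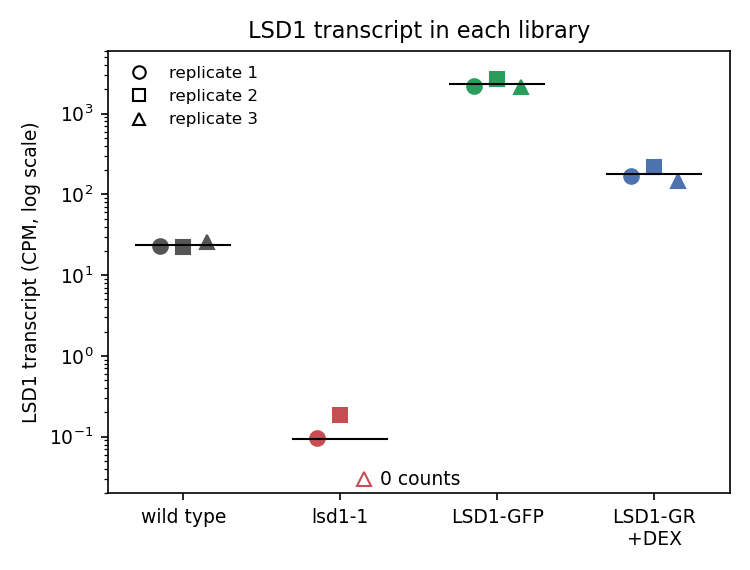
LSD1 transcript in each library, in TMM-scaled CPM on a log axis, by group; symbols are replicates, black bars are group means and the open symbol marks a library with 0 counts. The LSD1-GFP libraries sit near the group mean of 2351 CPM and the LSD1-GR+DEX libraries near 178 CPM, above the wild-type mean of 23.57 CPM.

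The comparison of lsd1-1 with wild type asks which transcripts depend on LSD1 in untreated rosettes. Genes of salicylic acid immunity were higher in the mutant: 26 of 33 members measured rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 difference of 1.42 (adjusted p = 2.64e-58, and adjusted p = 0.0152 with an estimated correlation). FMO1, a monooxygenase needed for systemic acquired resistance, rose from 0.25 ± 0.12 to 31.4 ± 11.1 CPM (n = 3 per group), a log2 difference of 6.91 (SE 0.47, adjusted p = 5.76e-06). EDS5, which exports the precursor of salicylic acid from plastids, rose 7.23-fold (log2 2.85, SE 0.20, adjusted p = 4.34e-06). PBS3, which acts in the next step of its synthesis, rose 3.95-fold (log2 1.98, SE 0.14), and DMR6, which hydroxylates salicylic acid, rose 2.36-fold (log2 1.24, SE 0.09). PR1, the best-known marker of this response, had 401 ± 78.7 CPM against 198 ± 97.3 CPM in wild type (log2 1.02, SE 0.65, adjusted p = 0.446) and was not called.

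Oxidative stress markers rose with them in lsd1-1, 12 of 18 called and 0 lower (16 and 0 adjusted over the list alone; median log2 1.31, adjusted p = 1.81e-15, and adjusted p = 0.207 with an estimated correlation). Among these, the alternative oxidase AOX1D rose by 3.36 (SE 0.48) and the mitochondrial stress marker BCS1 by 2.32 (SE 0.27) on the log2 scale. In the glucosinolate and camalexin list 7 of 20 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 3.03e-14, and adjusted p = 0.135 with an estimated correlation). The camalexin enzymes CYP71A12 (log2 3.25, SE 0.22) and PAD3 (3.22, SE 0.31) led it. CYP71A12 has a close paralog, CYP71A13, so the split of reads between them is uncertain. Heat shock and protein folding genes rose, 6 of 13 called and 0 lower (11 and 0 adjusted over the list alone; median 2.87, adjusted p = 1.42e-10, and adjusted p = 0.287 with an estimated correlation). HSP70 stood at 389, 1120 and 417 CPM in lsd1-1 replicates 1 to 3 and at 55.5, 180.5 and 65.9 CPM in wild type. The clock gene GI rose 3.42-fold (log2 1.77, SE 0.32, adjusted p = 0.00709), also with its highest value in replicate 2 of both groups. The HSP70 call (log2 2.67, SE 0.61, adjusted p = 0.029) is lost without wild type replicate 1 (log2 2.385, adjusted p = 0.107), wild type replicate 3 (2.441, 0.114) or lsd1-1 replicate 2 (1.999, 0.0688). With replicate number as a block HSP70 had a log2 difference of 2.682 (adjusted p = 0.00012), and 11 of the 13 genes were called higher and 0 lower (adjusted p = 3.39e-30 for the list with the preset correlation). The correlation estimated for this list without the block was 0.539, far above the preset 0.01, so that p-value overstates the evidence.

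Further lists rose in lsd1-1 with fewer members called. In ethylene and jasmonate defence 5 of 15 rose and 0 fell (8 and 1 adjusted over the list alone; adjusted p = 1.19e-05, and adjusted p = 0.308 with an estimated correlation). Among them were the ethylene synthesis gene ACS2 (log2 2.68, SE 0.35) and the chitinase HCHIB (1.28, SE 0.13). PDF1.2 was not called (0.94, SE 0.49, adjusted p = 0.322). In the MYC2 branch of jasmonate response 7 of 21 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.000155, and adjusted p = 0.479 with an estimated correlation). JAZ1, a repressor induced by jasmonate, had a log2 difference of 1.48 (SE 0.19). Among cell death regulators 4 of 17 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.00103, and adjusted p = 0.308 with an estimated correlation). They include RBOHD, the oxidase behind the defence oxidative burst (0.63, SE 0.09), and BAP1, a suppressor of cell death (2.06, SE 0.32). Senescence and starvation genes rose, 5 of 11 called and 0 lower (6 and 1 adjusted over the list alone; adjusted p = 0.00705, and adjusted p = 0.425 with an estimated correlation), a call lost without lsd1-1 replicate 2 (adjusted p = 0.0693). In the abscisic acid, cold and drought list 1 of 21 rose and 1 fell, over all genes and adjusted over the list alone (adjusted p = 0.0401, and adjusted p = 0.72 with an estimated correlation), a call lost without wild type replicate 3 (0.214) or lsd1-1 replicate 2 (0.469).

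Among called genes with at least 5 CPM in the higher group and no overlap between replicates, the largest rises in lsd1-1 were from near 0. AT5G63225, a carbohydrate-binding protein, was at least 109-fold higher and AT5G46960, an invertase inhibitor-like protein, at least 65.9-fold higher than in wild type, where neither had a count. BAP2, a paralog of BAP1, was 145-fold higher (counting interval 49.4 to 708) and BGLU27, a glucosidase, 93.4-fold higher (25.5 to 777). Within the same limits, the largest falls besides LSD1 were in AT1G27990 (from 6.04 ± 2.35 to 0.31 ± 0.54 CPM), the phosphate starvation RNA IPS1 (log2 -1.45, SE 0.29), the cytokinin-induced response regulator ARR7 (-1.40, SE 0.15), AT1G49200 (-1.38, SE 0.14) and the transcription factor BZIP61 (-1.37, SE 0.17). Nuclear photosynthesis genes gave no call (0 of 39; median log2 -0.02, adjusted p = 0.678), and of 26 antioxidant enzymes 1 was called over all genes and 0 adjusted over the list alone (adjusted p = 0.971). CSD1 (log2 0.12, SE 0.20), CSD2 (-0.13, SE 0.22), CAT2 (-0.03, SE 0.10) and RBCS1A (-0.12, SE 0.11) were not called. The list test did not pass for the other 12 lists either (adjusted p from 0.165 to 0.971). Of their members, 1 each was called higher in auxin response, cell cycle and cell wall and touch, 1 lower in floral transition and in epidermis, 1 higher and 2 lower in the clock, 1 and 1 in phosphate starvation, and 0 in anthocyanin, iron deficiency, root, guard cell and vascular lists. Adjusted over the list alone, the counts higher and lower differed for auxin response (1 and 1), cell cycle (4 and 0), clock (3 and 2), phosphate starvation (2 and 1) and epidermis (0 and 2). The test passed for anthocyanin without lsd1-1 replicate 1 (adjusted p = 0.0293), cell cycle without wild type replicate 3 (0.00866) or lsd1-1 replicate 1 (0.0433), and phosphate starvation without wild type replicate 2 (0.0192). For epidermis it passed without wild type replicate 3 (0.0485) or lsd1-1 replicate 2 (0.0227). Median, mean and test differed in sign for the antioxidant, clock, iron and vascular lists.

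In all, 1617 of 19487 genes were called between lsd1-1 and wild type (8.3%), 1012 higher and 605 lower, and 470 of the former and 39 of the latter changed at least 2-fold. Between replicates of the 2 groups 5182 genes did not overlap, where chance gives 10% of genes. Replicate numbers pair the libraries of these 2 groups, and with replicate number as a block 2889 genes were called, 1750 higher and 1139 lower, 1610 of them shared with the 1617. The block also moved further counts of calls by more than 1.5 times, higher and lower, to 11 and 0 in glucosinolate and camalexin, 6 and 1 in abscisic acid, cold and drought, 3 and 0 in anthocyanin, 3 and 2 in the clock and 2 and 0 in cell cycle. They became 1 and 1 in photosynthesis and in auxin response and 0 and 2 in epidermis, and the 9 list calls held. Against a fold change of 1.5, 251 genes passed, and the count was 764 without wild type replicate 1, 1060 without wild type replicate 3, 1053 without lsd1-1 replicate 1 and 975 without lsd1-1 replicate 2.

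The comparison of LSD1-GFP with wild type asks what a surplus of LSD1 does in untreated rosettes. The series holds no line with the fluorescent protein alone, so surplus LSD1, the fusion partner and the transgene insertion cannot be separated here. Nuclear photosynthesis genes rose as a group: 32 of 39 were higher and 1 lower (34 and 2 adjusted over the list alone), with a median log2 difference of 0.50 (adjusted p = 4.65e-15, and adjusted p = 0.333 with an estimated correlation). LHCB3, a light-harvesting protein of photosystem II, rose 2.27-fold from 1195 ± 142 to 2717 ± 223 CPM (n = 3 per group; log2 1.19, SE 0.11, adjusted p = 5.2e-06). LHCA4 of photosystem I rose 1.98-fold (log2 0.99, SE 0.08) and the Rubisco gene RBCS1A rose 1.39-fold (log2 0.48, SE 0.11). Antioxidant enzymes rose, 14 of 26 higher and 1 lower, over all genes and adjusted over the list alone (adjusted p = 5.82e-06, and adjusted p = 0.308 with an estimated correlation). Among them the ascorbate recycling enzymes DHAR1 (log2 1.52, SE 0.15) and MDAR1 (0.81, SE 0.09) and the superoxide dismutases CSD1 (0.95, SE 0.20) and CSD2 (0.96, SE 0.21) were higher. CAT2 was not called (0.04, SE 0.10, adjusted p = 0.833).

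Cold and drought genes were also higher in LSD1-GFP: 9 of 21 in the abscisic acid, cold and drought list rose and 0 fell (10 and 1 adjusted over the list alone; adjusted p = 4.78e-06, and adjusted p = 0.479 with an estimated correlation). RD29B, a drought-induced protein, rose 17.1-fold from 1.90 ± 0.16 to 32.7 ± 0.63 CPM (log2 4.1, SE 0.25, adjusted p = 1.79e-07). COR15A, a cold-induced chloroplast protein, rose 8.65-fold (log2 3.11, SE 0.28). In glucosinolate and camalexin synthesis 14 of 20 rose and 0 fell, over all genes and adjusted over the list alone (adjusted p = 6.4e-11, and adjusted p = 0.206 with an estimated correlation). They include CYP79F1 (1.43, SE 0.15) and the regulator MYB29 (0.94, SE 0.11) of the methionine-derived branch. In the MYC2 branch of jasmonate response 10 of 21 rose and 2 fell, over all genes and adjusted over the list alone (adjusted p = 0.000584, and adjusted p = 0.497 with an estimated correlation). The jasmonate synthesis enzyme AOS had a log2 difference of 1.61 (SE 0.08) and the repressor JAZ6 at -0.53 (SE 0.10). In anthocyanin and flavonoid synthesis 4 of 12 rose and 0 fell, over all genes and adjusted over the list alone (adjusted p = 0.00293, and adjusted p = 0.507 with an estimated correlation). It was led by FLS1 (1.49, SE 0.18) and TT4 (1.34, SE 0.18).

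Clock and heat shock genes moved together in LSD1-GFP. In the clock list 6 of 13 rose and 3 fell (6 and 4 adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.507 with an estimated correlation), a call lost without wild type replicate 3 (adjusted p = 0.0589). GI rose 8.43-fold (log2 3.08, SE 0.31), and PRR5, which peaks later in the day than the morning genes, rose 3.86-fold (log2 1.95, SE 0.21), while the morning gene RVE4 fell (-0.76, SE 0.09). Heat shock and protein folding genes rose, 7 of 13 called and 0 lower, over all genes and adjusted over the list alone (median 3.24, adjusted p = 5.05e-05, and adjusted p = 0.479 with an estimated correlation). HSP70 stood at 656, 1046 and 700 CPM in replicates 1 to 3 (log2 2.99, SE 0.62, adjusted p = 0.00629). Oxidative stress markers rose, 4 of 18 called and 0 lower (3 and 0 adjusted over the list alone; adjusted p = 0.0401, and adjusted p = 0.717 with an estimated correlation), a call lost without wild type replicate 3 (0.131) or LSD1-GFP replicate 2 (0.0898).

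Lower in LSD1-GFP were floral transition genes, of which 4 of 5 fell and 0 rose, over all genes and adjusted over the list alone (median -1.32, adjusted p = 1.64e-05, and adjusted p = 0.135 with an estimated correlation). The floral identity genes FUL (from 13.9 ± 1.36 to 2.55 ± 0.61 CPM, log2 -2.45, SE 0.17) and SEP3 (-2.34, SE 0.29) fell, as did SOC1 (-0.51, SE 0.09). PR1 fell from 198 ± 97.3 to 21.7 ± 9.44 CPM (log2 -3.20, SE 0.74, adjusted p = 0.0111). The salicylic acid list as a whole did not move (3 higher and 4 lower of 33, over all genes and adjusted over the list alone; adjusted p = 0.866), with WRKY18 higher (1.35, SE 0.22) and NIMIN3 lower (-0.93, SE 0.10). In senescence and starvation 6 of 11 fell and 1 rose (6 and 4 adjusted over the list alone; adjusted p = 0.0615), a test that passed without wild type replicate 1 (0.0444), wild type replicate 3 (0.0249) or LSD1-GFP replicate 1 (0.0248). DIN10 (-1.12, SE 0.12) and SEN1 (-0.98, SE 0.18) were among those that fell. AT5G61160 was among the largest falls of called genes with at least 5 CPM in wild type and no overlap between replicates (-3.55, SE 0.55), as were AT1G76530 (-3.24, SE 0.31) and AT1G27990 (-3.78, SE 0.80).

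Of called genes with at least 5 CPM and no overlap between replicates, the largest rises in LSD1-GFP besides LSD1 included AT3G59480, a sugar kinase-like protein (from 0.71 ± 0.24 to 106 ± 5.56 CPM, log2 7.19, SE 0.16), AT1G11070 (4.99, SE 0.18) and AT3G56920, a DHHC zinc finger protein (298-fold, counting interval 82.0 to 2460). AT5G20430 and AT5G20440, near-identical Mob1-like genes that lie side by side on chromosome 5, had no count in wild type and were at least 384-fold and at least 90.6-fold higher. Their neighbour CHR42, chosen after its values were seen, rose too (3.58, SE 0.20, adjusted p = 6.4e-08). The list test did not pass for the other 11 lists (adjusted p from 0.191 to 0.972). Cell death regulators had 3 higher and 2 lower, ethylene and jasmonate defence 2 and 3, iron deficiency 3 and 2, phosphate starvation 3 and 1, auxin response 1 and 2, cell cycle 3 and 0, cell wall and touch 0 and 2, epidermis 1 and 0, and the root, guard cell and vascular lists 0. Adjusted over the list alone, the counts differed for ethylene and jasmonate defence (3 and 4) and phosphate starvation (4 and 1). For cell cycle the test passed without wild type replicate 3 (0.0305) or LSD1-GFP replicate 1 (0.0312). Median, mean and test differed in sign for ethylene and jasmonate defence, auxin response and guard cell lists. Among cell death regulators the metacaspase MC2 fell (-1.63, SE 0.23).

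In all, 5662 of 19487 genes were called between LSD1-GFP and wild type (29.1%), 3017 higher and 2645 lower, of which 512 and 443 changed at least 2-fold. Replicate ranges did not overlap for 8295 genes, where chance gives 10%. Replicate numbers pair these libraries too, and with replicate number as a block 7309 genes were called, 5639 of them shared with the 5662. Counts of calls that the block moved by more than 1.5 times became, higher and lower, 11 and 0 in heat shock, 7 and 1 in oxidative stress, 2 and 0 in epidermis, 1 and 0 in root and guard cell markers and 1 and 1 in vascular markers, and the 10 list calls held. In iron deficiency they became 3 and 0, as IMA1 (adjusted p = 0.0166, 0.0518 with the block) and IMA2 (0.0457, 0.0902) were no longer called. Against a fold change of 1.5, 602 genes passed.

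The comparison of LSD1-GR+DEX with wild type asks what LSD1 does when it is moved into the nucleus by dexamethasone, but transgene, dexamethasone and transfer to new medium cannot be separated here. All 13 iron deficiency genes measured rose and 0 fell, over all genes and adjusted over the list alone, with a median log2 difference of 2.02 (adjusted p = 2.91e-14, and adjusted p = 0.206 with an estimated correlation). BHLH101, a transcription factor of the iron response, rose from 2.73 ± 0.66 to 25.6 ± 9.01 CPM (n = 3 per group; log2 3.23, SE 0.29, adjusted p = 4.3e-06), and BTS, an iron sensor and ubiquitin ligase, rose 4.06-fold (2.02, SE 0.16). Markers of root tissue had a median of 0.80, with 3 of 10 called higher (2 adjusted over the list alone), PYK10 by 1.14 (SE 0.16). Their mean was 4.039 and 4.287 log2 CPM in LSD1-GR+DEX replicates 1 and 3, against 3.11, 2.891 and 3.341 in wild type. In LSD1-GR+DEX replicate 2 it was 2.853, below every wild-type library. The root marker list test did not pass (adjusted p = 0.0975), but it did without LSD1-GR+DEX replicate 2 (adjusted p = 8.08e-05). In that library the mean over the iron list was 6.49 log2 CPM, against 7.18 and 7.18 in replicates 1 and 3. Wild type had iron list means of 5.13, 4.84 and 5.14, so replicate 2 stood higher in iron genes but not in root markers. Phosphate starvation genes rose, 6 of 9 called higher and 1 lower, over all genes and adjusted over the list alone (adjusted p = 0.000731, and adjusted p = 0.391 with an estimated correlation). The acid phosphatase PAP17 had a log2 difference of 1.66 (SE 0.24).

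Genes of anthocyanin, glucosinolate and jasmonate pathways were higher in LSD1-GR+DEX. In anthocyanin and flavonoid synthesis all 12 measured genes rose, over all genes and adjusted over the list alone (median 1.58, adjusted p = 5.29e-08, and adjusted p = 0.308 with an estimated correlation). The regulator PAP1 (log2 2.38, SE 0.40) and the enzyme DFR (2.04, SE 0.32) were among them. In glucosinolate and camalexin synthesis 17 of 20 rose and 0 fell, over all genes and adjusted over the list alone (adjusted p = 2.21e-18, and adjusted p = 0.124 with an estimated correlation). CYP71A12 was 17.0-fold (4.09, SE 0.22) and CYP83B1 3.39-fold higher (1.76, SE 0.13). In the MYC2 branch of jasmonate response 15 of 21 rose and 1 fell (16 and 1 adjusted over the list alone; median 1.36, adjusted p = 9.98e-08, and adjusted p = 0.333 with an estimated correlation). The jasmonate synthesis gene AOC2 rose from 8.15 ± 2.90 to 83.9 ± 6.47 CPM (3.35, SE 0.34) and JAZ1 by 2.26 (SE 0.19). In ethylene and jasmonate defence 9 of 15 rose and 1 fell, over all genes and adjusted over the list alone (adjusted p = 0.0117, and adjusted p = 0.497 with an estimated correlation). With replicate number as a block this list call was lost (adjusted p = 0.0589). The defensin PDF1.2 had a log2 difference of 3.00 (SE 0.50) and is one of a set of near-identical genes.

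Stress genes rose in LSD1-GR+DEX as well. In the oxidative stress list 14 of 18 rose and 0 fell (17 and 0 adjusted over the list alone; median 1.47, adjusted p = 6.63e-11, and adjusted p = 0.308 with an estimated correlation). BCS1 had a log2 difference of 3.24 (SE 0.27) and UPOX, a mitochondrial oxidative stress marker, at 2.91 (SE 0.24). Heat shock and protein folding genes rose, 12 of 13 called and 0 lower, over all genes and adjusted over the list alone (median 4.50, adjusted p = 2.91e-08, and adjusted p = 0.308 with an estimated correlation). HSP70 stood at 1693, 3422 and 1706 CPM in replicates 1 to 3 (log2 4.50, SE 0.66, adjusted p = 0.000817). The chaperone BIP2 of the endoplasmic reticulum rose 2.51-fold (1.33, SE 0.11), and small heat shock genes such as HSP17.4 (55.3 ± 63.8 CPM against 0.28 ± 0.15) had an SD above their mean. GI rose with them (log2 3.24, SE 0.31). AT1G53540, a small heat shock gene with no count in wild type, was at least 155-fold higher, a call (adjusted p = 0.0233) lost without wild type replicate 1 (0.0522) or 3 (0.059).

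Nuclear photosynthesis genes were lower in LSD1-GR+DEX, 23 of 39 called lower and 1 higher (25 and 1 adjusted over the list alone; median log2 -0.30, adjusted p = 7.29e-05, and adjusted p = 0.653 with an estimated correlation). Plastocyanin PETE1 fell to 94.6 ± 5.01 from 177 ± 15.3 CPM (-0.90, SE 0.11) and the photosystem I subunit PSAF fell too (-0.73, SE 0.13). Of called genes with at least 5 CPM in wild type and no overlap between replicates, the largest falls were FTM1 (from 17.3 ± 5.77 to 1.02 ± 0.52 CPM, log2 -4.06, SE 0.44), AT5G39890 (-3.07, SE 0.28), the response regulator ARR15 (-2.99, SE 0.32), AT1G33055 (-2.86, SE 0.26), AT4G36850 (-2.82, SE 0.15) and the growth regulator HBI1 (-2.81, SE 0.20). The expansin EXPA1 (-1.99, SE 0.20), the iron superoxide dismutase FSD1 (-1.22, SE 0.19) and LOL1, a relative of LSD1 that promotes cell death (-1.63, SE 0.16), also fell. Of 33 salicylic acid genes 10 rose and 4 fell (11 and 4 adjusted over the list alone; adjusted p = 0.385), with WRKY70 higher (1.17, SE 0.17), PBS3 lower (-1.02, SE 0.17) and PR1 not called (-1.44, SE 0.67, adjusted p = 0.129). CSD1 rose (0.77, SE 0.20), while CSD2 (0.29, SE 0.22, adjusted p = 0.32) and CAT2 (-0.09, SE 0.10, adjusted p = 0.532) were not called.

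In the other 12 lists the test did not pass (adjusted p from 0.0775 to 0.949). Members called higher and lower were 7 and 3 of 17 cell death regulators, 7 and 4 of 26 antioxidant enzymes, 3 and 5 of 13 clock genes, 2 and 4 of 11 in senescence and starvation, 1 and 5 of 21 in abscisic acid, cold and drought, 4 and 0 of 12 in cell cycle, 1 and 3 of 9 in cell wall and touch, 2 and 1 of 10 in auxin response, 0 and 2 of 5 in floral transition, 0 and 1 of 6 in epidermis, and 0 in the guard cell and vascular lists. Adjusted over the list alone, the counts were 9 and 3 for cell death regulators, 8 and 4 for antioxidant enzymes, 4 and 5 for the clock and 3 and 4 for senescence, and did not differ for the rest. Cell cycle passed without wild type replicate 3 (0.0096) or LSD1-GR+DEX replicate 2 (0.0473), and cell wall and touch without wild type replicate 3 (0.0316). Median, mean and test differed in sign for the clock, senescence and guard cell lists. In all, 7015 of 19487 genes were called (36%), 3760 higher and 3255 lower, of which 1248 and 414 changed at least 2-fold. Replicate ranges did not overlap for 9164 genes, where chance gives 10%. Against a fold change of 1.5, 1305 genes passed.

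**Figure D2:**
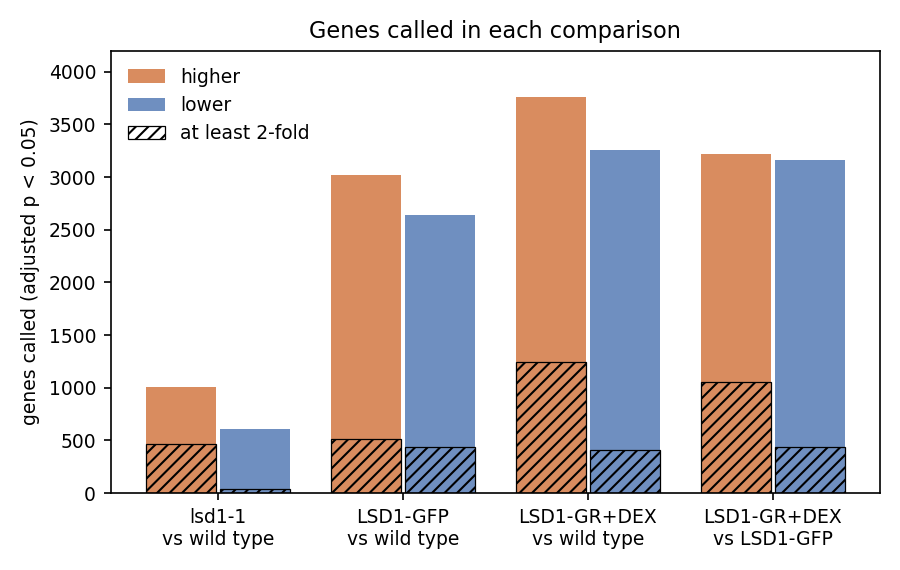
Genes called higher and lower in each of the 4 comparisons at an adjusted p below 0.05; hatched parts are genes that changed at least 2-fold. The bars run from 605 genes lower in lsd1-1 to 3760 genes higher in LSD1-GR+DEX.

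The comparison of LSD1-GR+DEX with LSD1-GFP tests directly whether the 2 overexpression lines differ, with dexamethasone, transfer and fusion partner changing together. Of 39 nuclear photosynthesis genes 36 were lower and 1 higher in LSD1-GR+DEX (37 and 1 adjusted over the list alone), with a median log2 difference of -0.71 (adjusted p = 6.56e-30, and adjusted p = 0.206 with an estimated correlation). LHCB1.3, a light-harvesting protein with near-identical paralogs, stood at 3184 ± 94.3 CPM against 10368 ± 825 in LSD1-GFP (n = 3 per group; log2 -1.70, SE 0.13, adjusted p = 7.1e-07). PSAN of photosystem I was lower as well (-1.33, SE 0.10). Iron deficiency genes were higher, 12 of 13 and 0 lower, over all genes and adjusted over the list alone (median 1.69, adjusted p = 4.65e-15, and adjusted p = 0.206 with an estimated correlation). BHLH101 had a log2 difference of 4.01 (SE 0.32) and the iron signalling peptide gene IMA1 at 3.07 (SE 0.26). Root markers stood at a median of 0.92 (4 of 10 higher and 0 lower, over all genes and adjusted over the list alone; adjusted p = 0.06), a test that passed without LSD1-GFP replicate 2 (adjusted p = 0.0366) or LSD1-GR+DEX replicate 2 (1.71e-05).

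Cold and drought genes were lower in LSD1-GR+DEX than in LSD1-GFP, 13 of 21 and 1 higher, over all genes and adjusted over the list alone (adjusted p = 2.69e-07, and adjusted p = 0.404 with an estimated correlation). RD29B had a log2 difference of -4.70 (SE 0.27) and COR15A at -2.71 (SE 0.27). Antioxidant enzymes were lower, 13 of 26 and 1 higher (15 and 1 adjusted over the list alone; adjusted p = 5e-04, and adjusted p = 0.404 with an estimated correlation). DHAR3 had a log2 difference of -0.88 (SE 0.08) and FSD1 at -1.21 (SE 0.19). Clock genes were lower, 7 of 13 and 0 higher, over all genes and adjusted over the list alone (adjusted p = 0.0117, and adjusted p = 0.497 with an estimated correlation). PRR5 had a log2 difference of -1.58 (SE 0.20). Oxidative stress markers were higher, 11 of 18 and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 4.78e-06, and adjusted p = 0.479 with an estimated correlation). UPOX had a log2 difference of 3.29 (SE 0.25). Anthocyanin genes were higher, 6 of 12 and 0 lower, over all genes and adjusted over the list alone (adjusted p = 0.0117, and adjusted p = 0.626 with an estimated correlation). PAP1 had a log2 difference of 2.07 (SE 0.39). In glucosinolate and camalexin synthesis 10 of 20 were higher and 3 lower, over all genes and adjusted over the list alone (adjusted p = 0.00685, and adjusted p = 0.497 with an estimated correlation), where PAD3 was higher (2.95, SE 0.30) and MYB29 lower (-1.03, SE 0.11).

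Defensin genes were among the largest rises of this comparison in genes with at least 5 CPM and no overlap between replicates. PDF1.3 was 419-fold higher in LSD1-GR+DEX than in LSD1-GFP (counting interval 116 to 3470), and PDF1.2 stood at 259 ± 92.5 CPM against 8.06 ± 3.64 (log2 5.01, SE 0.58, adjusted p = 0.00019). In their list, ethylene and jasmonate defence, 8 of 15 were higher and 4 lower (9 and 4 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.497 with an estimated correlation). In the MYC2 branch 9 of 21 were higher and 1 lower, over all genes and adjusted over the list alone (adjusted p = 0.0401, and adjusted p = 0.702 with an estimated correlation), a list call lost without LSD1-GFP replicate 2 (0.076) or 3 (0.0836) or LSD1-GR+DEX replicate 2 (0.33). AOC2 had a log2 difference of 2.48 (SE 0.32). Heat shock and protein folding genes were higher, 5 of 13 and 0 lower (6 and 0 adjusted over the list alone; median 1.51, adjusted p = 0.0158, and adjusted p = 0.667 with an estimated correlation), a call lost without LSD1-GR+DEX replicate 2 (0.142). BIP1 had a log2 difference of 0.84 (SE 0.10). Phosphate starvation genes were higher, 4 of 9 and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.0158, and adjusted p = 0.497 with an estimated correlation), a call lost without LSD1-GFP replicate 2 (0.0512). SQD2 had a log2 difference of 1.16 (SE 0.12). Floral transition genes were higher, 4 of 5 and 0 lower, over all genes and adjusted over the list alone (median 1.32, adjusted p = 0.0389, and adjusted p = 0.391 with an estimated correlation), a call lost without LSD1-GFP replicate 2 (0.104). It was also lost with replicate number as a block (adjusted p = 0.107). FUL had a log2 difference of 1.45 (SE 0.17). Within these limits the largest falls included AT5G20430 (at least 383-fold lower), AT4G25580 (199-fold, counting interval 54.7 to 1650), AT1G11070 (-6.32, SE 0.21) and the sucrose transporter SUC5 (-4.76, SE 0.20).

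In the other 9 lists the test did not pass between LSD1-GR+DEX and LSD1-GFP (adjusted p from 0.228 to 0.93). Members called higher and lower were 7 and 3 of 33 salicylic acid genes, 5 and 1 of 17 cell death regulators, 3 and 1 of 11 in senescence and starvation, 1 and 3 of 9 in cell wall and touch, 1 and 1 of 10 in auxin response, 0 and 2 of 6 in epidermis, 0 and 1 of 6 in guard cells, and 0 in the cell cycle and vascular lists. Adjusted over the list alone, the counts differed for senescence (4 and 1) and auxin response (1 and 0). Median, mean and test differed in sign for the guard cell list. In all, 6386 of 19487 genes were called (32.8%), 3223 higher and 3163 lower, of which 1055 and 436 changed at least 2-fold. LSD1 itself was lower in LSD1-GR+DEX (log2 -3.72, SE 0.16). Replicate ranges did not overlap for 8846 genes, where chance gives 10%. Against a fold change of 1.5, 1140 genes passed. Of the list calls in all 4 comparisons, that of salicylic acid immunity in lsd1-1 held with an estimated correlation and the others did not.

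**Figure D3:**
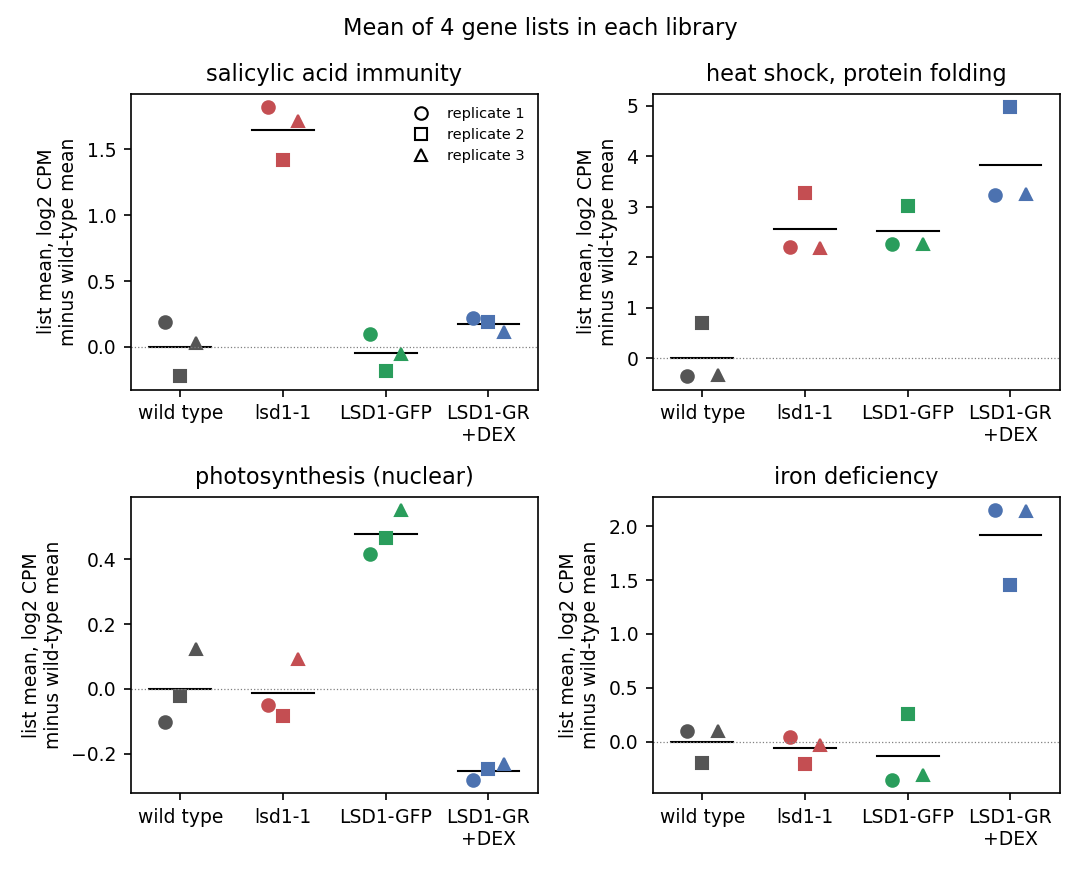
Mean of 4 gene lists in each library, as log2 CPM minus the wild-type mean, by group; symbols are replicates and black bars group means. Salicylic acid genes stand higher in lsd1-1, iron deficiency genes in LSD1-GR+DEX and heat shock genes in the 3 lines than in wild type, and photosynthesis genes are higher in LSD1-GFP and lower in LSD1-GR+DEX.

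Many genes were called in the same direction in lsd1-1, with little LSD1 transcript, and in the lines with more of it. Between lsd1-1 and LSD1-GR+DEX, 1308 genes were called in both comparisons with wild type, 1293 of them in the same direction (763 higher and 530 lower, where independence would give 195 and 100.9) and 15 in opposite directions (9 higher in lsd1-1 and 6 lower, against 169 and 117). Between lsd1-1 and LSD1-GFP, 820 were called in both, 733 in the same direction (387 higher and 346 lower, against 157 and 82.0 by independence) and 87 in opposite directions (54 higher in lsd1-1 and 33 lower, against 137 and 93.5). Between LSD1-GFP and LSD1-GR+DEX, 3034 were called in both, 2640 in the same direction (1333 higher and 1307 lower, against 582 and 442) and 394 in opposite directions (217 higher in LSD1-GFP and 177 lower, against 504 and 510). LSD1 was left out of these counts, and independence takes no account of shared wild-type libraries. A shared difference of wild type in hour of harvest or handling would also give calls in the same direction, and it was not tested here.

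These comparisons share their wild-type libraries, which alone gives correlation across genes. The simulations of unchanged groups cover the chance spread of shared libraries, not a systematic difference of wild type. Over 19486 genes, log2 differences of lsd1-1 and LSD1-GR+DEX had a Pearson r of 0.63 (Spearman rho 0.657) and a covariance of 0.207, against 0.0233 in 30 simulations of unchanged groups. For lsd1-1 and LSD1-GFP r was 0.361 (rho 0.405) and the covariance 0.099, against 0.0234, and for LSD1-GFP and LSD1-GR+DEX r was 0.449 (rho 0.45) and the covariance 0.167, against 0.0234. Simulated r was 0.496 to 0.499, above the r of the 2 pairs with LSD1-GFP. The share of genes with the same sign was 75.7% for lsd1-1 and LSD1-GR+DEX (66.5% in simulation), 64.3% for lsd1-1 and LSD1-GFP (66.6%) and 66.8% for LSD1-GFP and LSD1-GR+DEX (66.5%). For lsd1-1 and LSD1-GFP both r and sign thus lay below the simulated values, and for the 2 overexpression lines r lay below and sign close to them, while the covariances lay above. The simulated groups have no differences of their own, so their r and sign reflect shared libraries alone. Differences particular to 1 line can lower both, so values below simulation cannot be read as less agreement than chance. The 3 wild-type libraries are too few to give each comparison 2 of its own. A relation with no shared library was also computed, chosen after the data were seen. LSD1-GFP enters it with a minus sign, so it asks whether lsd1-1 resembles LSD1-GR+DEX more than LSD1-GFP. It cannot show whether lsd1-1 and the overexpression lines moved in the same direction. The lsd1-1 minus wild type differences and the LSD1-GR+DEX minus LSD1-GFP differences had r = 0.339 (rho 0.325), against -0.002 in simulation, and the same sign in 61.8% of genes, against 49.9%. Of 913 genes called in both, 805 had the same direction (510 higher and 295 lower, against 167 and 98 by independence) and 108 the opposite (60 higher in lsd1-1 and 48 lower, against 164 and 99.9). Genes are not independent replicates, and 4 relations were computed in this family.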

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

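The tests of heat shock genes, of the chromosome 5 neighbours, of iron deficiency genes and of other splits of the libraries were chosen after the results they test had been seen. The lines LSD1-GFP and LSD1-GR+DEX differed from each other in the direction of photosynthesis genes: the list stood above wild type in the former and below it in the latter, and its median log2 difference between them was -0.707 (36 of 39 members called lower in LSD1-GR+DEX, adjusted p = 6.56e-30, and adjusted p = 0.206 with an estimated correlation). Across all genes, 394 were called in opposite directions in the 2 lines, 217 higher in LSD1-GFP and lower in LSD1-GR+DEX and 177 the other way. Independence would give 504 and 510, so opposite calls were fewer than that, and the direct test of these genes adds nothing, since they were selected for opposite calls. Of the 394, 18 were photosynthesis list members. Dexamethasone, transfer and fusion partner change together between these lines, and a difference in hour of harvest was not tested on these genes.

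Heat shock genes were higher than in wild type in all 9 libraries of the 3 lines, and GI rose in each line. A later hour of harvest of the lines may play a part but cannot be told apart from an effect of the lines. Of 4 dawn and 8 later clock genes, 2 were called the way of a later hour in lsd1-1. The number was 8 in LSD1-GFP and 7 in LSD1-GR+DEX, and of these 12 genes 0 were called against it in any line. ELF3 of the clock list is not among the 12. In lsd1-1 ELF3 was called lower, a call lost without wild type replicate 1 (log2 -0.332, adjusted p = 0.0921) or lsd1-1 replicate 3 (-0.358, 0.0655). In LSD1-GR+DEX 5 members of the clock list were called lower, while the 12 hold 4 dawn genes. The 0 thus covers the 12 chosen genes, not the whole list. By sign alone, 9 of 12 went that way in lsd1-1, 12 of 12 in LSD1-GFP and 12 of 12 in LSD1-GR+DEX. The clock list test passed in LSD1-GFP (adjusted p = 0.013) and not in lsd1-1 (0.971) or LSD1-GR+DEX (0.886). That test cannot decide here, since a later hour moves dawn and later genes in opposite directions. Warmth or handling that also moves GI cannot be told apart either: the heat shock mean and GI deviated from their group means with Pearson r = 0.903 over 12 libraries (Spearman rho = 0.818, r = 0.899 without the 2 farthest), but replicate 2 was highest for HSP70 and GI in every group, and moving the numbers in all groups at once allows 6 arrangements and no p below 0.167. An effect of LSD1 itself stays open and was not tested apart from these.

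CHR42 and the Mob1-like genes AT5G20430 and AT5G20440, 3 neighbours on chromosome 5, were all higher in LSD1-GFP. In this line 31 genes rose at least 8-fold. Random gene orders gave a run of 3 such genes with a share of 3e-04 (2 of 10000 orders, with the real order counted as 1 more). This share cannot decide on chance placement, since the run was seen before the test was chosen. The test also takes genes as independent, while the 2 near-identical Mob1-like genes may share reads. Reads shared between the near-identical Mob1 genes do not explain CHR42, which is no Mob1 gene and rose by 3.58 (SE 0.20). The rise was absent in LSD1-GR+DEX, where both Mob1-like genes had 0 counts. CHR42 stood there at 0.984, 0.769 and 0.858 CPM, against 1.06, 0.987 and 1.70 CPM in wild type. LSD1 itself rose 7.55-fold in LSD1-GR+DEX and 99.7-fold in LSD1-GFP, so this cannot decide on an effect of LSD1. A transgene insertion or a foreign chromosome segment next to these genes cannot be told apart from an effect of LSD1: the median over 10 flanking genes was 0.31, with MGD2 (1.04, SE 0.32) and PHT4;5 (0.61, SE 0.15) on one side and XIK (0.47, SE 0.09) and AT5G20500 (0.36, SE 0.09) on the other called higher, and the series maps no insertion.

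All 13 iron deficiency genes rose in LSD1-GR+DEX, against 3 higher and 2 lower in LSD1-GFP (median difference between these lines 1.69, adjusted p = 4.65e-15) and 0 called in lsd1-1, from which the difference was not tested. More root tissue in these samples is argued against as the whole cause, since the list median exceeded the root marker that rose most, PYK10 at 1.14 (SE 0.16), by 0.88. Without LSD1-GR+DEX replicate 2 the iron median was 2.14 and the highest root marker EXPA7 at 1.44 (SE 0.24), and part of the rise could still come from roots. LSD1 transcript abundance alone is argued against, since the list median in LSD1-GFP, with more LSD1 transcript, was -0.23. Dexamethasone or the transfer to new medium cannot be told apart from the fusion protein, because 0 untreated LSD1-GR libraries were analysed.

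Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. Every other split mixes the 2 groups on both sides, so a real difference widens its spread and makes few calls likely. The counts of other splits thus cannot decide on chance. In edgeR fits of the 2 groups alone the real split called 1596 genes for lsd1-1, 5145 for LSD1-GFP, 6151 for LSD1-GR+DEX and 5691 between the latter lines, and was the 1 split of 10 with as many. The highest count among the other splits was 0 in each, with at most 2031, 1125, 1474 and 1467 genes at an unadjusted p below 0.05, against 3992, 7457, 8326 and 7857 in the real splits. For lsd1-1 and LSD1-GFP, where replicate numbers pair the libraries, 3 other splits part as many pairs as the real one, and these too called 0.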

How the results depend on the processing

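One test here, the relation between contrasts without a shared library, was chosen after the data were seen. RLE size factors, the DESeq2 test, limma voom, both filters and fits of 2 groups left the 4 counts of called genes within 1.5 times. They gave 1476 to 1793 for lsd1-1, 5145 to 5645 for LSD1-GFP, 6151 to 7062 for LSD1-GR+DEX and 5691 to 6404 between the lines. For LSD1-GR+DEX it is unclear whether the numbers pair the libraries. Correlations of same-numbered libraries 1 to 3 were 0.035, 0.22 and 0.314 with wild type and -0.034, 0.123 and 0.328 with LSD1-GFP. Those of other numbers averaged -0.099 and -0.071, but not every same-numbered pair was above 0.1. With the numbers as a block, 8541 and 8027 genes were called against wild type and LSD1-GFP. Ethylene and jasmonate defence against wild type (adjusted p = 0.0589) and floral transition between the lines (0.107) were no longer called. Against wild type PR1 (0.0417) and CSD2 (0.0111) were called. Of 6 libraries, 4 and 3 correlated best with their own number in these comparisons. In LSD1-GFP the block ended the calls of IMA1 (0.0518), IMA2 (0.0902) and AT5G22430 (0.0553), and it changed no other call of a named gene or list. Replicate number as a block gave 2889 genes for lsd1-1, and without single libraries its count ran from 764 to 1375; fewer samples leave less power. A test against 1.5-fold called 251, 602, 1305 and 1140 genes, as it asks for a larger change. Of the 9, 10, 9 and 13 lists called, 1, 0, 0 and 0 held when camera estimated the correlation, which widens its error, while fry's mixed test called 14, 20 and 20 in the comparisons with wild type. The estimate was 0.223 for salicylic acid in lsd1-1, 0.584 for iron deficiency in LSD1-GR+DEX against wild type and 0.511 for photosynthesis between the lines. All estimates were above the preset 0.01, the lowest at 0.013, so p-values with the preset understate the error. Of 437 results for named genes, lists and relations, 61 lost a call without at least 1 of the libraries, 11 gained one, 27 changed direction and 339 did none of these. No named gene or list changed direction with RLE size factors, which ended 2 calls (BCS1 in LSD1-GFP, COBL9 in LSD1-GR+DEX). The DESeq2 test ended 3 (SEP3 in lsd1-1, FT and IAA19 between the lines) and made 1 (PR1 between the lines), and no low-count filter ended 11. Directional fry ended 3 list calls (abscisic acid, cold and drought in lsd1-1, oxidative stress in LSD1-GFP, the MYC2 branch between the lines) and made 6. Depth limits genes with few counts: with 0 in a group the fold is a lower bound, and with 1 to 3 a ratio with a wide interval.

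No gene or list that was called changed direction. Values below are log2 differences, or list medians, of results not called, whose sign or test direction turned; the cause was not tested. With fry these were antioxidants (-0.025) and clock (0.002) in lsd1-1, auxin in LSD1-GFP (0.071) and guard cells in LSD1-GR+DEX (0.024). With the block they were clock in lsd1-1 (0.004), and auxin (0.067) and clock (0.205) in LSD1-GR+DEX. Ranges without single libraries were, in lsd1-1, CSD1 -0.02 to 0.279, RBCS1A -0.187 to 0.004, CAT2 -0.102 to 0.067, antioxidants -0.057 to 0.046, photosynthesis -0.069 to 0.042, anthocyanin 0.049 to 0.544, cell wall -0.114 to 0.194, clock -0.088 to 0.094, iron -0.067 to 0.145, root -0.044 to 0.214 and vascular -0.136 to 0.266. In LSD1-GFP they were CAT2 -0.053 to 0.137, salicylic acid -0.201 to 0.015, auxin -0.101 to 0.224, iron -0.298 to -0.106, root -0.21 to 0.073, guard cell -0.138 to 0.036 and vascular -0.01 to 0.353. In LSD1-GR+DEX they were CAT2 -0.179 to 0.011, antioxidants -0.038 to 0.109, auxin -0.109 to 0.153, clock 0.047 to 0.444, senescence -0.052 to 0.197 and guard cell -0.043 to 0.088. Between the lines they were cell cycle 0 to 0.343, guard cell -0.055 to 0.224 and vascular -0.061 to 0.268.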

Other observations

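The type-A response regulator and low-oxygen lists were written after ARR7, ARR15, FTM1, AT5G39890 and AT1G33055 had been seen among the largest falls of genes with at least 5 CPM and no overlap between replicates, and their tests leave these genes out and were chosen before the values of the other members were seen. Type-A response regulators, which cytokinin induces and which damp its signal, were lower than in wild type in all 3 lines. Of 7 other members measured, 5 fell in lsd1-1 (median log2 -0.79, adjusted p = 7.07e-10, and adjusted p = 0.0384 with an estimated correlation), 6 in LSD1-GFP (-1.40, adjusted p = 9.34e-11, and adjusted p = 0.0384 with an estimated correlation) and 6 in LSD1-GR+DEX (-1.34, adjusted p = 5.72e-08, and adjusted p = 0.0531 with an estimated correlation), and 0 rose. ARR6 fell from 73.0 CPM in wild type to 28.9 in lsd1-1 (-1.34, SE 0.16), 18.5 in LSD1-GFP (-1.98, SE 0.17) and 27.7 in LSD1-GR+DEX (-1.40, SE 0.16), and the list mean of all 3 libraries of each line lay below the lowest wild-type library. Between LSD1-GR+DEX and LSD1-GFP the list did not pass (0.30, 1 higher and 0 lower, adjusted p = 0.644). A lower response to cytokinin in the 3 lines may be a hypothesis for this, but no cytokinin measurement is at hand, and a shared difference of wild type in its hour of harvest was not tested on these genes.

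Low-oxygen genes, which plants switch on when oxygen is short, were lower in LSD1-GR+DEX than in wild type. Of 10 other members, 7 fell and 2 rose (median log2 -1.57, adjusted p = 0.000177 over 8 tests of these lists, and adjusted p = 0.1 with an estimated correlation), with the list mean below the lowest wild-type library in 3 of 3 libraries. The alcohol dehydrogenase ADH1 fell from 25.4 to 3.97 CPM (-2.67, SE 0.23), the sucrose synthase SUS4 by 2.01 (SE 0.25) on the log2 scale and the oxygen-sensing enzyme gene PCO1 by 2.33 (SE 0.26), while HRE2 (3.5, SE 0.42) and the haemoglobin HB1 (0.95, SE 0.24) rose. In lsd1-1 the median was -0.04 with 0 of 10 called and in LSD1-GFP 0.20 with 1 higher (adjusted p = 0.82 and 0.527). Against LSD1-GFP the LSD1-GR+DEX median was -1.72 (adjusted p = 9.95e-06, and adjusted p = 0.0772 with an estimated correlation). More oxygen around the seedlings moved on mesh to new medium could be a candidate explanation beside an effect of the fusion protein, and the design does not separate them.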
